A study of Mus musculus with 6 samples.

How the data were processed

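The series holds 6 Affymetrix mouse arrays, 3 hybridised with RNA from Clcn5 knockout and 3 with RNA from wild type proximal tubules, and the groups were taken from the sample titles. Per the labels, total RNA was extracted with Trizol, pooled over mice, amplified in 1 round from an oligo dT primer and labelled with biotin. The deposited values are signal intensities on a linear scale, made by the authors with GCOS 1.4 and MAS5, per the submitters' processing notes. The table showed a trimmed mean of 150 on every array, with 2% of the probe sets trimmed at each end, and no other normalization between arrays is stated. Because primers start at the poly(A) tail, the probes read mostly the ends of transcripts. The ratio of signals from the 3′ and 5′ probes was 1.10 to 1.36 for actin and 0.74 to 0.83 for Gapdh. MAS5 detection calls are not part of the table used here, so no probe set could be called above or below background, and fold changes of dim probe sets are less certain. Between 39.0% and 44.2% of the probe sets of an array had a signal under 32. The experiment records of the arrays, which are text and hold no measurement, were read for the fluidics station, the solution lot and the pool description.

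The table has 45101 probe sets, of which 64 are controls and were left out. Of the other 45037, 34945 carry 1 gene symbol in the platform annotation, 932 several and 9160 none, and a gene was named only from probe sets with 1 symbol. Of those 34945 probe sets, 34754 had a gene identifier found in the mouse RefSeq table, and no symbol needed updating. The files name no genome build, so the RefSeq table served only for names and for the order of genes, and no coordinates are given.

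Signals were turned to log2 without a pseudocount, since all were above 0. A probe set was kept if its mean log2 signal over all 6 arrays reached the median of the probe sets that are not controls, which corresponds to a signal of 41.9, and 22519 were kept. Each gene was represented by its kept probe set with the highest mean, which left 11620 genes out of 18194 on the array. Of the 753 changed genes, 375 had another kept probe set, and in 295 of these every other one had the same direction. Knockout was compared with wild type by lmFit and eBayes with an intensity trend in limma 3.58.1 under R 4.3.3, two-sided, with 4 residual degrees of freedom and Benjamini-Hochberg adjustment over the tested genes at 0.05. An unadjusted p under 0.05 was reached by 2249 genes, where 581 are expected by chance. Means and SDs are of the linear signals of 3 arrays. Log2 changes, SEs and fold changes come from the fit, and a fold change is the ratio of geometric means. Tables were prepared and plotted with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

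There were 38 gene lists, 23 of functions and 15 of cell types or sexes, written with 622 entries before the data were examined, as were the comparisons, the rule for named genes and the other settings. Of the entries, 571 are on the array, 3 of them under an updated symbol. The 36 lists with 3 or more tested members were tested with camera at a preset correlation of 0.01, adjusted over these lists, and again with a correlation estimated per list and with fry. Some genes belong to more than 1 list. The named genes are Clcn5 with all its probe sets, the 15 largest log2 changes in each direction among genes past the threshold whose groups do not overlap, up to 4 members with the smallest p of each list that passed camera or had at least 2 members past the threshold, and up to 2 of any other list. A direction with fewer than 10 qualifying genes would have been filled up to 10 with the smallest unadjusted p, which did not arise. Other genes are named where it is said that they were chosen after their values were seen. Neighbours of Clcn5 on the X chromosome were compared with the other genes by Fisher's exact test.

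The steps were tested on simulated data with 11620 genes, 3 arrays against 3 and 200 changed genes, in 10 simulations of the comparison of knockout with wild type. The share of changed genes recovered was 40.4% at a log2 change of 0.5, 82.2% at 1 and 98.6% at 2, all with the right sign, and 4.9% of the calls were false. A list of 30 genes shifted by −0.3 was called in all 10 simulations, and 1 unchanged list was called. The genes were drawn independently of each other, with variances from the fit's own prior, and all members of the list shifted alike. In the data the estimated correlation was 0.18 for the PPARα list and 0.60 for the respiratory chain. The simulations therefore do not show how often lists of correlated genes are called falsely.

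Alternatives changed the transform of the signal, the normalization between arrays, the filter on dim probe sets, the choice of probe set, the variance model, the array weights, the station as a block, a block by array number, the threshold and the list test, and left out each array in turn. A fit within station 1 alone and the mixed form of fry were added after the data were seen. Probe sets without a single symbol were tested apart from the genes.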

Results

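Transcript levels were measured in proximal tubules dissected in ice-cold salt solution from the kidneys of Clcn5 knockout and wild type mice. Clcn5 encodes ClC-5, a chloride/proton exchanger of the endosomes of proximal tubule cells, and its loss in humans causes Dent disease, in which small filtered proteins and calcium are lost into the urine. Each array carried biotin-labelled RNA pooled from the tubules of several mice, with 80 to 100 tubule pieces of 2 mm taken from each kidney. The labels give 3 to 4 mice per pool, while the records stored with the arrays give 7 mice per pool, and the difference could not be settled. There were 3 arrays of knockout pools and 3 of wild type pools. The records call the arrays of a group biological replicates, so that the p-values given here measure the spread between RNA pools. The values are signals of Affymetrix mouse arrays, scaled to a trimmed mean of 150 on each array. The median signal of an array lay between 40.9 and 45.3 on 5 arrays and was 48.8 on knockout array 3. Pearson's r of the log2 signals, across genes, was 0.978 to 0.986 within a group and 0.967 to 0.977 between the groups. The number of arrays limits the precision: the median standard error of a log2 change was 0.115.

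Clcn5 itself was lower in the knockout tubules on all 4 of its probe sets and on every array. The probe set that represented the gene, 1420295_x_at, fell from a signal of 917 ± 181 (SD, n = 3) in wild type to 314 ± 41.8 (SD, n = 3) in knockout, which is 2.89-fold lower (log2 change −1.53, SE 0.14, limma adjusted p = 9.32e-05). Probe set 1429400_at showed the largest drop of the 4, 7.31-fold, from 839 ± 20.4 to 115 ± 10.3. Probe sets 1450787_at and 1441831_x_at were 4.28-fold and 2.83-fold lower. Both groups were present on each of the fluidics stations used for washing and staining. The log2 change was −1.53 with the station as a block and −1.60 on station 1, and on station 2 the signals of 1420295_x_at were 269 in knockout and 709 in wild type. The sources used here do not give which part of the gene was deleted, so a probe set outside that part would not test the labels.

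**Figure D1:**
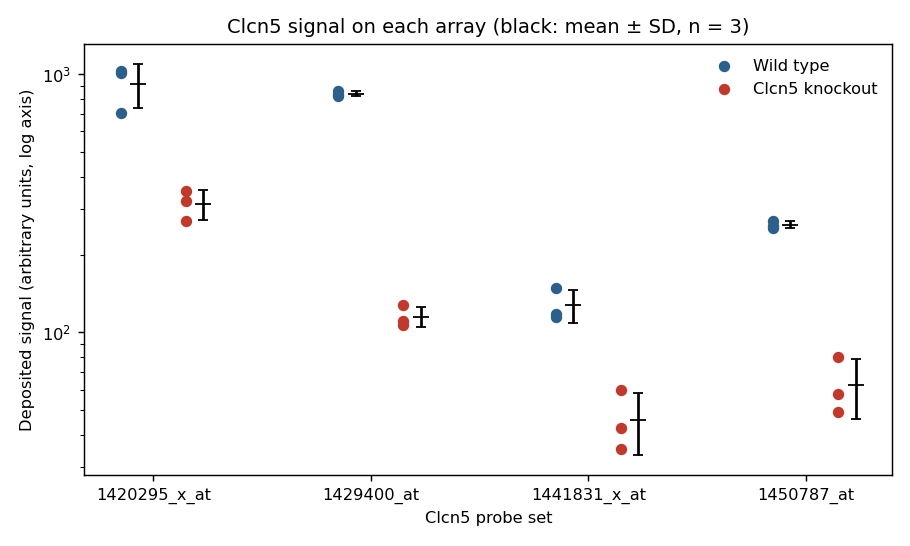
Deposited signal (vertical log axis, arbitrary units) of the 4 Clcn5 probe sets (horizontal axis) on each array, wild type in blue and Clcn5 knockout in red, with black marks for the mean ± SD (n = 3). The knockout arrays lie below the wild type arrays for every probe set, with means of 115 against 839 for 1429400_at.

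The comparison asked which other transcripts of the dissected tubule samples differ when Clcn5 is disrupted. Among the largest rises was Slc10a2, the apical sodium-dependent bile acid transporter, with a fitted change of 17.3-fold from a dim signal in wild type (signal 313 ± 56.3 against 18.0 ± 2.22, SD, n = 3; log2 change 4.11, SE 0.19). The gene that fell most was Cyp4a14, a fatty acid omega-hydroxylase and target of PPARα, which was 33.8-fold lower (32.9 ± 7.62 against 1100 ± 120; log2 change −5.08, SE 0.16). Rnase4, a secreted ribonuclease, was 15.6-fold lower (77.5 ± 13.5 against 1200 ± 15.3), and Gdpd3, a lysophospholipase D, was 11.4-fold higher (408 ± 58.1 against 36.0 ± 6.68). None of Slc10a2, Cyp4a14, Rnase4 and Gdpd3 had another kept probe set to compare with. Of 11620 genes tested with limma, Clcn5 included, 753 changed at an adjusted p under 0.05, 377 of them higher and 376 lower in knockout. In all 753 the 3 knockout values did not overlap the 3 wild type values, and 2927 of all tested genes, 25.2%, had such groups, where chance gives 10%. Most changes were small: 104 of the 753 genes changed by 2-fold or more, 44 of them higher and 60 lower. The signals of this table come without detection calls, so a low signal such as that of Slc10a2 in wild type could not be told from background. With 50 added to every signal Gdpd3 (log2 change 2.41) stood before Slc10a2 (2.40). The count was 487 when the variances were moderated without a trend on intensity, and leaving out 1 array gave 512 to 733 genes. The higher genes numbered 248 without wild type array 2, and the lower ones 250 and 246 without wild type arrays 1 and 3.

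Among the 15 largest rises were also Cap1, an actin-binding protein of the cyclase-associated family, at 4.94-fold (785 ± 22.7 against 159 ± 10.6), and Ppard, which encodes the nuclear receptor PPARδ, at 4.10-fold (333 ± 28.4 against 83.1 ± 21.8). Tmem267 rose 4.64-fold, Abhd1 4.27-fold and Tmem87a 4.23-fold. Lyz1, which encodes a lysozyme, rose 4.02-fold, from a signal of 27.4 ± 8.11 in wild type. The others were Rpgrip1, Ocel1, Prxl2b, Mcm6, Mfsd2a, Arntl and Hpf1, between 2.97-fold and 3.82-fold higher. Among the 15 largest falls, Cyp24a1, the enzyme that inactivates vitamin D hormone, dropped 6.50-fold (log2 change −2.70, SE 0.10), and Pttg1, which encodes securin, 3.91-fold (553 ± 112 against 2130 ± 131). Ces1g, a carboxylesterase of lipid metabolism, was 3.05-fold lower and Etnppl, which breaks down phosphoethanolamine, 3.64-fold lower. Nkain1, Cyb5d2, Nxpe3, Nap1l5 and F5, which encodes coagulation factor V, were 3.13-fold to 3.88-fold lower. The remaining 4 falls were less firm. Ing1 was 3.46-fold lower, but without any of the wild type arrays another probe set represented it and its log2 change was −0.48 to −0.23, with an adjusted p up to 0.44. With all arrays the log2 change of Ing1 was −0.37 under quantile normalization (limma adjusted p = 0.136) and −0.67 with averaged probe sets (0.00569). The calls of Nucb2, Osr2 and Fam241a ended without some arrays: without each of the wild type arrays for Nucb2 (adjusted p up to 0.077), without knockout array 2 for Osr2 (0.0653), and without knockout array 2 or wild type array 2 for Fam241a (up to 0.106). Osr2 and F5 were too dim for the filter when any of 3 arrays was left out, and Fam241a for any of 2. Without knockout array 3 the log2 changes of Nucb2 and Fam241a were −1.20 and −1.17. With 50 added to every signal all 30 genes passed again, but the log2 changes of dim ones were smaller. Among the rises they were 2.40 for Slc10a2, 2.41 for Gdpd3, 1.37 for Tmem87a, 1.04 for Mcm6 and 1.03 for Lyz1. Among the falls they were −3.79 for Cyp4a14, −3.30 for Rnase4, −1.20 for Etnppl, −1.04 for Nucb2, −1.01 for Cyb5d2, −0.88 for F5, −0.83 for Nap1l5 and Osr2 and −0.80 for Fam241a.

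**Figure D2:**
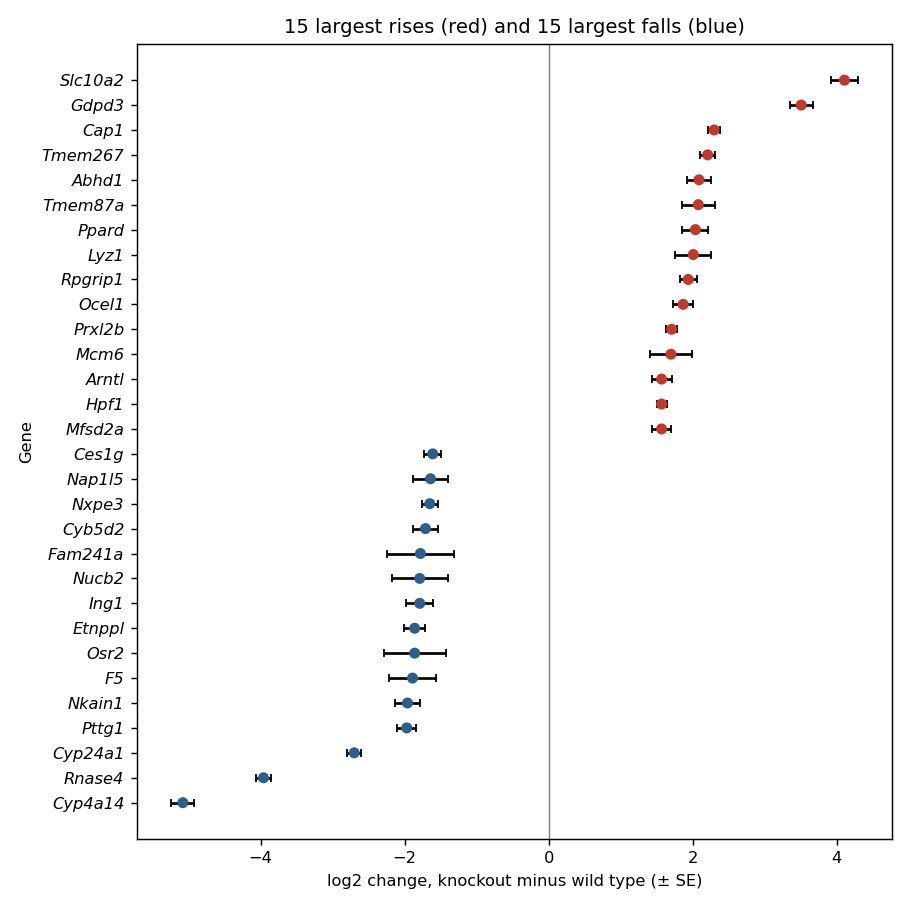
Log2 change, knockout minus wild type (horizontal axis), of the 15 genes with the largest rise (red) and the 15 with the largest fall (blue) among genes past the threshold; points are the fitted changes and bars their SE, from 3 arrays per group. The changes run from −5.08 for Cyp4a14 to 4.11 for Slc10a2.

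Genes of fatty acid oxidation and other PPARα targets were lower in the knockout tubules. Of 22 tested members of this list, 12 fell and none rose, and 17 fell when the p-values were adjusted over the list alone. Cyp4a14 fell most, followed by Plin2, the coat protein of lipid droplets, which was 2.69-fold lower (465 ± 56.5 against 1250 ± 121). Vnn1, a pantetheinase, was 2.36-fold lower (844 ± 82.4 against 1990 ± 42.4), and Acot1, an acyl-CoA thioesterase, 2.30-fold lower (272 ± 44.1 against 621 ± 45.3). The median log2 change of the list was −0.46, and it was −0.49 on station 1 and −0.38 on station 2. On the same arrays the medians were −0.14 for markers of the S1 and S2 segments, 0.51 for leukocytes and 0.39 for podocytes. The list stood below other genes by camera with its preset correlation (adjusted p = 5.52e-17), and not with an estimated correlation (adjusted p = 0.12). No list passed with an estimated correlation, where 7 of the 36 tested lists had an unadjusted p under 0.05, against 9 that passed with the preset one. By fry, which asks whether the average change of a list's members differs from 0, 13 lists passed. They were the 9 called by camera except the thick ascending limb (adjusted p = 0.055), with cholesterol synthesis (0.00192), complement and acute phase (0.018), carbonic anhydrases (0.018), S1 and S2 markers (0.0426) and adipocytes (0.000768). Only 1 of 3 adipocyte markers, Car3, was above 0, and 5 of 10 carbonic anhydrases were. Car3, with a log2 change of 1.49, is in both lists, and whether they pass without it was not tested.

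Genes of sterol and fatty acid synthesis included a few that rose. Sqle, the squalene epoxidase of cholesterol synthesis, was 2.05-fold higher (924 ± 24.4 against 450 ± 23.8). Hmgcs1, which makes HMG-CoA for the same pathway, was 1.58-fold higher (5160 ± 151 against 3270 ± 337), and Idi1 had a log2 change of 0.48. Of 20 tested members of the cholesterol list, 3 rose and 1 fell, which was Sc5d, 1.34-fold lower, and 5 and 2 did so adjusted over the list alone. The list did not pass camera (median log2 change 0.10, adjusted p = 0.144) but passed fry (adjusted p = 0.00192). Of 15 fatty acid synthesis genes, 2 rose, also adjusted over the list alone. They were Acss2, the cytosolic acetyl-CoA synthetase, at 1.39-fold, and Acly, ATP citrate lyase, at 1.18-fold (camera adjusted p = 0.101). The calls of Sc5d, Acss2 and Acly each ended without at least 2 of the 6 arrays, with adjusted p up to 0.077, 0.0728 and 0.148.

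Among genes of vitamin D, calcium and phosphate handling, 2 rose and 2 fell out of 19 tested, and 3 and 2 did so adjusted over the list alone. Besides Cyp24a1, the sodium-phosphate cotransporter gene Slc34a3 fell, 1.80-fold (448 ± 68.9 against 798 ± 45.1). The genes of calbindin, Calb1, and of the sodium-calcium exchanger Slc8a1 were 1.35-fold and 1.44-fold higher. The other kept probe sets of Calb1 had log2 changes of 0.77, 0.77 and 1.23. The call of Slc8a1 ended when its probe sets were averaged (adjusted p = 0.351). Both are expressed in the distal convoluted and connecting tubule, and Calb1 is on its marker list, which had a median log2 change of 0.28. Their rises can therefore not be assigned to the proximal tubule. Cyp27b1, which makes the hormone, and its receptor gene Vdr, both singled out after their values were seen, had log2 changes of 0.17 (adjusted p = 0.311) and 0.18 (adjusted p = 0.164). The list did not pass camera (adjusted p = 0.259), and its median of 0.11 and its mean of −0.07 differed in sign.

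Transporters of the proximal tubule moved singly. Of 29 tested genes for sugar, amino acid and ion transport, 1 rose and 3 fell, and 2 and 3 did so adjusted over the list alone. The neutral amino acid transporter gene Slc6a19 was 1.42-fold lower (1950 ± 76.7 against 2760 ± 93.2), and Slc7a7, of the basolateral carrier of cationic amino acids, 1.39-fold lower (1970 ± 56.3 against 2730 ± 138). Slc6a19 is also a marker of the S1 and S2 segments, whose list had a median log2 change of −0.14. Slc13a2, of the sodium-dicarboxylate cotransporter, was 1.27-fold lower and Slc6a18 1.20-fold higher. Their calls ended without 3 and 5 of the 6 arrays, with adjusted p up to 0.0633 and 0.174. Of 19 organic ion and drug transporters, 1 rose and 1 fell, with the same counts adjusted over the list alone: Abcc4, an efflux pump, was 1.52-fold higher (527 ± 28.7 against 346 ± 18.4) and Slco3a1 1.49-fold lower (631 ± 11.8 against 939 ± 15.9). Neither list passed camera (adjusted p = 0.252 and 0.893), and the median of the latter, 0.05, and its mean, −0.04, differed in sign. Of 10 tested carbonic anhydrases, which interconvert carbon dioxide and bicarbonate, 2 rose and 1 fell, and 4 and 1 did so adjusted over the list alone. Car3 was 2.80-fold higher (4310 ± 136 against 1540 ± 75.2) and Car14 1.30-fold lower (823 ± 18.2 against 1070 ± 39.8). Car15 was 1.29-fold higher, a call that ended without knockout array 2 or wild type array 1 or 2 (adjusted p up to 0.0628), and the list did not pass camera (adjusted p = 0.202) but passed fry (adjusted p = 0.018).

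The receptors and machinery of apical endocytosis, the process in which ClC-5 takes part, showed no shift as a list at the transcript level. Of 29 tested members, none rose and 1 fell by limma, Ehd1, with a log2 change of −0.26, a call that ended without each array except knockout array 1 (adjusted p up to 0.15). None passed adjusted over the list alone. The lowest member, the clathrin adaptor gene Ap2b1, was at −0.33 (adjusted p = 0.0919), with its other kept probe set at −0.24. The receptor genes Lrp2 (megalin), Cubn (cubilin) and Amn, and the adaptor gene Dab2, singled out after their values were seen, had log2 changes of 0.05, −0.03, 0.00 and −0.08. Their 95% intervals ran from −0.11 to 0.21, −0.19 to 0.12, −0.15 to 0.15 and −0.24 to 0.09. The other kept probe sets of Dab2 were at −0.06, −0.06 and −0.31. The list did not pass camera (median 0.02, mean −0.01, adjusted p = 0.661). None of 18 V-ATPase subunits, which acidify endosomes, passed limma's threshold, over all genes or adjusted over the list alone (camera adjusted p = 0.327). Those with the smallest p were Atp6v0a1, at −0.46 (adjusted p = 0.0674), and Atp6ap1, at 0.22 (adjusted p = 0.104). Of 13 CLC family and other chloride channel genes, 1 rose, also adjusted over the list alone. This was Clcn3, of the related endosomal exchanger ClC-3, at 1.78-fold (2130 ± 71.1 against 1200 ± 79.4), and the list did not pass camera (adjusted p = 0.668).

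Lysosomal genes were lower as a list by camera (median log2 change −0.10, adjusted p = 0.00052), but not with an estimated correlation (adjusted p = 0.226). Of 30 tested members, 5 fell and 1 rose, and 6 and 1 did so adjusted over the list alone. Hexa, the alpha subunit of beta-hexosaminidase, was 2.17-fold lower (166 ± 2.78 against 361 ± 3.03), Gusb, beta-glucuronidase, 1.80-fold lower (201 ± 22.1 against 361 ± 9.32) and Lipa, lysosomal acid lipase, 1.34-fold lower. Ppt1, a palmitoyl-protein thioesterase, was 1.45-fold higher (722 ± 28.9 against 499 ± 17.5), a call that ended when its probe sets were averaged (adjusted p = 0.357). The list's median was −0.12 on station 1 and −0.10 on station 2. On the same arrays the markers of the S1 and S2 segments of the proximal tubule had a median of −0.14 (camera adjusted p = 0.0602, and under 0.05 in some other settings), and those of leukocytes and podocytes had medians of 0.51 and 0.39.

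Early response and stress genes, which rise when tissue is handled, were higher in the knockout tubules. Of 20 tested members, 13 rose and none fell, and 17 rose adjusted over the list alone. Zfp36, which encodes an RNA-binding protein that destabilises messenger RNAs, was 1.82-fold higher (1250 ± 25.6 against 689 ± 5.17). The transcription factor gene Jund was 1.42-fold higher (1590 ± 73.3 against 1120 ± 52.6) and the phosphatase gene Dusp1 1.38-fold higher (1630 ± 58.7 against 1180 ± 29.0). The median log2 change was 0.41, with 0.44 on station 1 and 0.31 on station 2. The list passed camera (adjusted p = 1.54e-14) and not with an estimated correlation (adjusted p = 0.0822). Markers of leukocytes and podocytes were higher on the same arrays, with medians of 0.51 and 0.39.

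Genes on the list of the unfolded protein response were lower as a list by camera (median log2 change −0.07, adjusted p = 0.0349), but not with an estimated correlation (adjusted p = 0.226). The call ended under a stricter filter on dim probe sets (adjusted p = 0.115) and without knockout array 1 (0.0933). Of 17 tested members, 4 fell and none rose, and 5 fell adjusted over the list alone. Chac1, which degrades glutathione, was 1.80-fold lower (100 ± 10.9 against 180 ± 20.8) and Asns, asparagine synthetase, which also answers to a lack of amino acids, 1.68-fold lower (144 ± 18.5 against 241 ± 5.08). Xbp1, a transcription factor of the unfolded protein response, was 1.26-fold lower. The chaperone gene Dnajb9 was 1.32-fold lower, a call that ended without knockout array 1 or 3 or wild type array 1 or 2 (adjusted p up to 0.0726). The list's median was −0.07 on station 1 and −0.09 on station 2, on arrays where it was −0.14 for S1 and S2 markers, 0.51 for leukocytes and 0.39 for podocytes. Of 22 antioxidant and NRF2 genes, 3 fell and none rose, with the same counts adjusted over the list alone (camera adjusted p = 0.132). Camera called the antioxidant list lower with quantile normalization (adjusted p = 0.0291), averaged probe sets (0.0105), within station 1 (0.0309) and without wild type array 2 (0.0491). Hmox1, heme oxygenase, was 2.28-fold lower (153 ± 43.9 against 342 ± 43.1), and Gclc, of glutathione synthesis, 1.35-fold lower. Gsta2, a glutathione transferase, was 1.27-fold lower, a call that ended without each of the wild type arrays (adjusted p up to 0.0728).

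Clock genes moved in opposite directions. Arntl, which encodes BMAL1, was 2.97-fold higher (167 ± 10.2 against 56.6 ± 6.13). Its other kept probe set had a log2 change of −0.06, and the gene had 0.75 in place of 1.57 when its probe sets were averaged. Dbp was 1.92-fold lower (511 ± 84.2 against 970 ± 55.5) and Hlf 1.29-fold lower. Bhlhe40 was 1.25-fold lower, a call that ended without wild type array 1 or 3 (adjusted p up to 0.064). Of 13 tested members of the circadian list, 1 rose and 4 fell, and 1 and 5 did so adjusted over the list alone (camera adjusted p = 0.0919, and 0.00232 under a stricter filter on dim probe sets). Per2, singled out after its value was seen, was 1.52-fold lower (limma adjusted p = 0.0353). Camera looks for a shift in 1 direction, so members moving in opposite directions count against each other. The time of day of dissection is not given in the sources used here.

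Markers of tubule injury were mixed, in samples where the leukocyte list had a median log2 change of 0.51. Havcr1, which encodes the injury marker KIM-1, was 2.29-fold higher (110 ± 6.74 against 48.3 ± 5.77), and Clu, clusterin, 1.47-fold higher (2820 ± 71.3 against 1930 ± 107). The fibrinogen chain genes Fga and Fgg, which rise in injured tubules, were 1.94-fold and 1.91-fold lower, the call of Fgg ending without wild type array 3 (adjusted p = 0.0523). Of 14 tested members, 3 rose and 2 fell, and 4 and 2 did so adjusted over the list alone (camera adjusted p = 0.215). Of 20 genes of fibrosis and extracellular matrix, 2 rose, and 3 adjusted over the list alone. They were the collagen gene Col4a1, at 1.31-fold (1530 ± 71.3 against 1160 ± 31.5), and Ccn2, at 1.25-fold, whose call ended without each array except knockout array 3 (adjusted p up to 0.169; camera adjusted p = 0.247). Of 13 cell cycle genes, 1 rose and 1 fell, also adjusted over the list alone: the replication helicase gene Mcm6, at 3.25-fold (151 ± 40.1 against 48.1 ± 20.6), and Ccnd1, 1.17-fold lower, whose call ended without any of the 6 arrays (adjusted p up to 0.247; camera adjusted p = 0.24). None of 15 interferon response genes and none of 8 complement and acute phase genes passed limma's threshold over all genes or adjusted over the list alone (camera adjusted p = 0.362 and 0.132), and the medians of these lists were −0.10 and 0.21. The complement list passed fry (adjusted p = 0.018).

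Genes of energy metabolism other than fatty acid oxidation showed no shift as lists by camera under the main settings. Over all tested genes 6.5% passed limma's threshold. None of 25 tested respiratory chain genes passed limma's threshold over all genes or adjusted over the list alone, and their log2 changes lay between −0.07 and 0.12 (median 0.05, camera adjusted p = 0.233, and 0.00353 in the direction of higher signals without wild type array 3). Of 13 gluconeogenesis and ammoniagenesis genes, 1 fell, and 2 adjusted over the list alone. This was Slc38a3, the glutamine transporter that feeds ammonia production, 1.69-fold lower (118 ± 14.5 against 199 ± 2.35; camera adjusted p = 0.234 for the list, and 0.0442 with quantile normalization), a call that ended when its probe sets were averaged (adjusted p = 0.178). Of 15 glycolysis and hypoxia genes, 1 rose and 1 fell, and 2 and 1 did so adjusted over the list alone (camera adjusted p = 0.874). These were Pkm, pyruvate kinase, with a log2 change of 0.32, and Bnip3, with −0.27, and each call ended without 5 of the 6 arrays (adjusted p up to 0.143 and 0.152).

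Some markers of other kidney cell types rose in the knockout samples. Leukocyte markers rose in 4 of 12 cases, 6 adjusted over the list alone, and all 12 had a log2 change above 0. The antigen presentation genes Cd74 and H2-Aa were 1.66-fold (1100 ± 29.4 against 662 ± 45.0) and 1.61-fold (1500 ± 92.1 against 928 ± 30.4) higher, and the macrophage receptor gene Csf1r had a log2 change of 0.58. The list's median was 0.51, with 0.51 on station 1 and 0.56 on station 2 (camera adjusted p = 3.17e-07, and adjusted p = 0.0822 with an estimated correlation). Of 7 podocyte markers, 2 rose, and 4 adjusted over the list alone. Synpo, synaptopodin, was 1.66-fold higher (200 ± 9.55 against 121 ± 12.1), and Nphs1, nephrin, 1.56-fold higher, a call that ended without knockout array 2 or wild type array 1 or 3 (adjusted p up to 0.0726). The median was 0.39, with 0.40 on each station (camera adjusted p = 0.000353, and adjusted p = 0.12 with an estimated correlation).

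Some markers of intercalated cells, the distal convoluted and connecting tubule and the thick ascending limb rose, while 2 principal cell markers fell. Of 6 intercalated cell markers 2 rose, and 3 adjusted over the list alone (median 0.24, with 0.24 on station 1 and 0.36 on station 2). Slc4a1, of the anion exchanger, was 1.49-fold higher (382 ± 19.5 against 256 ± 25.7), and Slc26a4, pendrin, 1.21-fold higher, a call that ended without each array except knockout array 2 (adjusted p up to 0.102). The list passed camera (adjusted p = 0.00594) and not with an estimated correlation (adjusted p = 0.201). Of 6 markers of the distal convoluted and connecting tubule 3 rose, also adjusted over the list alone (median 0.28, with 0.28 on station 1 and 0.30 on station 2). Pvalb, parvalbumin, was 1.38-fold higher (473 ± 7.61 against 345 ± 25.6) and Calb1 1.35-fold higher, while Slc12a3, the thiazide-sensitive cotransporter, had a log2 change of −0.12 (adjusted p = 0.56; singled out after its value was seen). Trpm6 was 1.31-fold higher, a call that ended without each array except knockout array 2 (adjusted p up to 0.121). Camera called the list (adjusted p = 0.0144), but not with averaged probe sets (0.0812) or with an estimated correlation (adjusted p = 0.225). Of 8 markers of the thick ascending limb 2 rose, and 3 adjusted over the list alone (median 0.15, with 0.14 on station 1 and 0.18 on station 2). Umod, uromodulin, was 1.33-fold higher (5150 ± 269 against 3880 ± 217), and Slc12a1 1.21-fold higher, a call that ended without each array except knockout array 3 (adjusted p up to 0.154). Camera called the list (adjusted p = 0.0433), but not after median centring (0.0634), without knockout array 2 (0.169) or wild type array 1 (0.0701), or with an estimated correlation (adjusted p = 0.318).

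Other cell type lists did not pass camera. Of 7 principal cell markers 2 fell, and 3 fell and 1 rose adjusted over the list alone (median −0.06, camera adjusted p = 0.234). The water channel gene Aqp3 was 1.45-fold lower (626 ± 48.0 against 905 ± 60.5) and Aqp2 had a log2 change of −0.49, a call that ended without each array except knockout array 1 (adjusted p up to 0.16). None of 10 endothelial markers and none of 6 markers of fibroblasts, pericytes and smooth muscle passed limma's threshold over all genes or adjusted over the list alone (median −0.02 and 0.17, camera adjusted p = 0.893 and 0.259). Of 3 adipocyte markers 1 rose, also adjusted over the list alone, which was Car3. Their median of −0.08 and mean of 0.43 differed in sign (camera adjusted p = 0.234, fry adjusted p = 0.000768). Of the proximal tubule's own markers, 1 of 6 for the S1 and S2 segments fell, Slc6a19, and 1 of 6 for the S3 segment rose, Slc7a13, a cystine and aspartate carrier that was 1.29-fold higher (4780 ± 166 against 3690 ± 57.8). The counts were the same adjusted over the list alone (camera adjusted p = 0.0602 and 0.247). The S1 and S2 list was called lower by camera with quantile normalization (adjusted p = 0.00753), with no filter on dim probe sets (0.0338), with each probe set on its own (0.0132), within station 1 (0.0363), and without knockout array 2 (0.0211) or wild type array 2 (0.0195). With the preset correlation its adjusted p ran up to 0.169, without knockout array 1, it was 0.369 with an estimated correlation, and it passed fry (adjusted p = 0.0426). Slc7a13 was also the single riser among 7 male-biased kidney genes, where 1 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.259). None of 4 sex-chromosome genes passed over all genes or adjusted over the list alone (camera adjusted p = 0.651). The erythroid list, whose 1 tested member was Slc4a1, and the female-biased list, whose 2 tested members did not pass, were too short for camera.

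**Figure D3:**
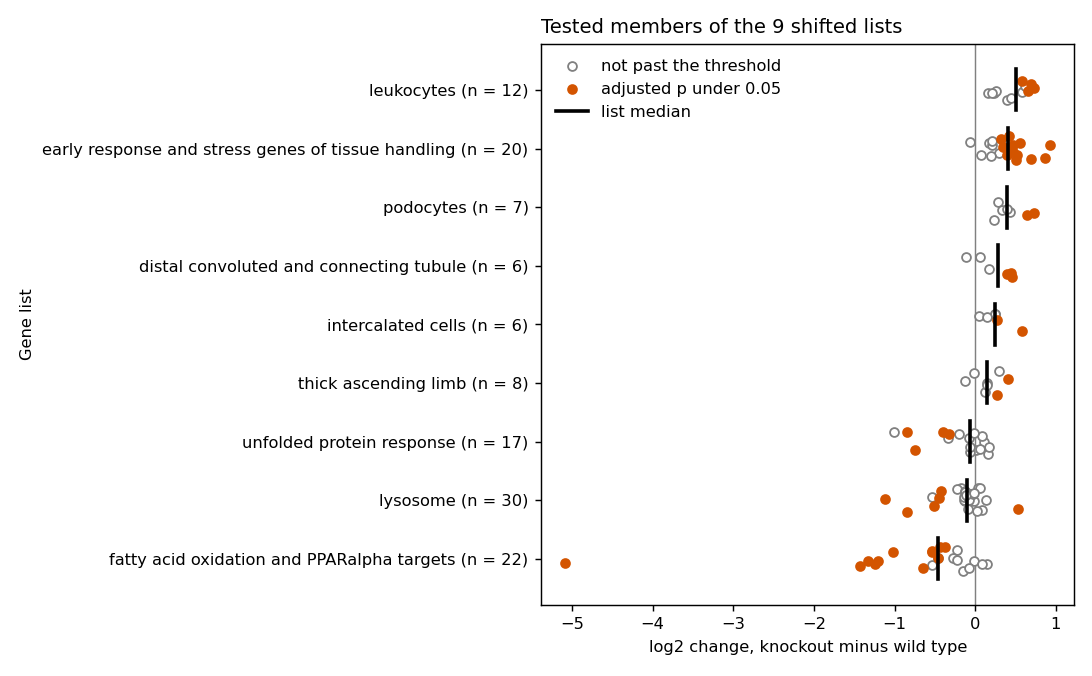
Log2 change, knockout minus wild type (horizontal axis), of each tested gene in the 9 lists that camera called with its preset correlation; filled points are genes with adjusted p under 0.05, open points the rest, and black bars the list medians. The medians run from −0.46 for fatty acid oxidation and PPARα targets to 0.51 for leukocytes.

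**Figure D4:**
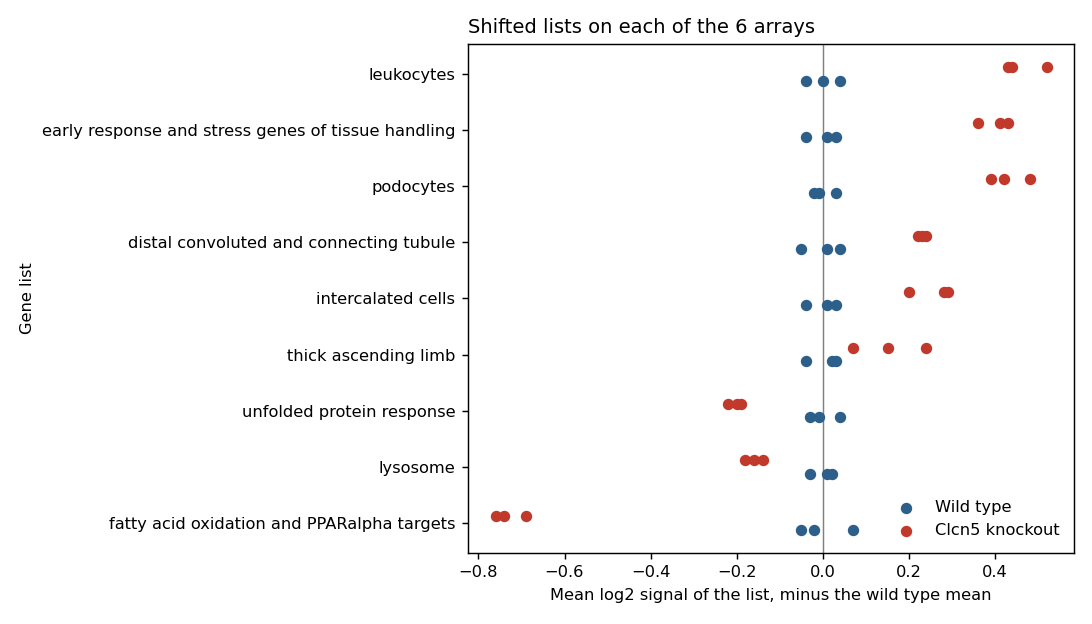
Mean log2 signal of the 9 called lists on each array, minus the mean of the wild type arrays (horizontal axis), with wild type arrays in blue and knockout arrays in red. The 3 knockout arrays lie on the same side of all 3 wild type arrays in each list, at −0.69 to −0.76 for fatty acid oxidation and PPARα targets.

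The batches recorded with the arrays were set against the group difference. All arrays were scanned on 1 day. Station 1 held knockout arrays 1 and 2 and wild type arrays 1 and 3, and station 2 the other 2 arrays. With the station as a block 731 genes passed, 694 of them among the 753, and all 9 lists were called again. Within station 1 alone, with 2 arrays per group, 453 genes passed, 419 of them among the 753. Of the genes given above with their values, Chac1, Fgg, Hlf, Hmox1 and Xbp1 were among those not passing there (adjusted p 0.0568 to 0.0701), and Gclc, Hlf, Slc8a1 and Xbp1 did not pass without a trend of the variance on intensity (0.0507 to 0.0783). Station 2 had 1 array of each group and gave no test. Knockout array 3 alone was recorded with another lot of solution, whose use the records read here do not name, and had the highest median signal. Without this array 675 genes passed, 340 higher and 335 lower, 603 of them among the 753.

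Genes next to Clcn5 on the X chromosome were compared with the rest, since a targeted locus can keep flanking DNA of another strain. Among the genes within 50 gene positions of Clcn5, 1 of 28 tested had changed (3.6%), against 751 of 11591 elsewhere (6.5%). The odds ratio was 0.535 (95% interval 0.013 to 3.25; two-sided Fisher's exact test, p = 1). The changed neighbour was Hdac6, a deacetylase gene, with a log2 change of 0.27 (adjusted p = 0.0487; named after its value was seen).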

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

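The tests of neighbouring genes over all changed genes, of windows of genes, and of the split of the cell types into separate lists were chosen after the results were seen; the other tests were planned before their results. Probe sets with no gene symbol or with several stand outside the comparison of genes, and 118 of the 2859 kept ones changed in knockout by limma, 55 higher and 63 lower. That is 4.1%, against 4.8% of the kept probe sets with 1 symbol. The probe sets 1443620_at and 1423072_at were higher, with log2 changes of 1.52 (SE 0.09, signal 527 ± 5.22 against 184 ± 18.5, SD, n = 3) and 1.41 (SE 0.14). The probe sets 1423858_a_at and 1458719_at were lower, with log2 changes of −3.59 (SE 0.21, 33.1 ± 10.4 against 386 ± 41.2) and −2.57 (SE 0.29).

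Large changes of single genes, 104 by 2-fold or more with Clcn5 counted, may for genes other than Clcn5 come from strain differences in DNA rather than from its loss. Sequence variants under single probe sets are argued against for the 34 of these genes with a further kept probe set. There the next brightest one followed with a median ratio of log2 changes of 0.76 (95% bootstrap interval 0.61 to 0.96), although 7 ratios were under 0.25. The rest of the genes, Slc10a2, Cyp4a14, Rnase4 and Gdpd3 among them, could not be tested. Clcn5 is 1 of the 34, with a ratio of 1.87. Blocks of DNA from another strain stay open, since the 3 pairs of neighbouring genes of different families both changed by 2-fold or more (Cap1 with Mfsd2a, Pik3c2a with Nucb2, and Tmem267 with Ccl28 in opposite directions, of which Pik3c2a and Ccl28 were named after their values were seen) only reached the upper end of the 95% range of 10000 random placements (permutation p = 0.0531). Over the changed genes placed on a chromosome, Clcn5 left out, there were 79 such pairs. Random placements gave a median of 47 and an upper end of 59 (permutation p = 1e-04, the smallest they can give). A window of 20 tested genes held up to 9 changed ones against an upper end of 8 (permutation p = 0.00899). Shared regulation of neighbours, for which the 51 pairs moving in the same direction speak (upper end of shuffled directions 48), is open as well, as is the knockout itself, which was not tested apart from strain.

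Markers of other kidney cell types were higher in knockout, which may reflect carry-over in dissection or a change in the tissue. Some of these markers were bright in both groups. In wild type the signals were 7300 for Klk1, 3880 for Umod and 2850 for Slc12a3, next to 4180 for Lrp2 of the proximal tubule. In knockout they were 7600, 5150 and 2600, next to 4320. Signals of different probe sets do not give shares of cells, but a change in these samples cannot be assigned to the proximal tubule alone. A lower share of proximal tubule cells with every other type rising alike is argued against, since the medians of principal cells (−0.06, 95% bootstrap interval −0.49 to 0.13) and endothelium (−0.02, −0.09 to 0.07) lay below that of the 39 markers of the raised lists together (0.28, 0.23 to 0.41). These intervals resample markers and not arrays, and the raised lists were picked on the same data. Principal cell markers were mixed, from −0.53 for Aqp3 to 0.28 for Scnn1g. On knockout arrays 1 to 3 the endothelial list mean stood at 0.01, −0.07 and 0.03 relative to wild type. It stood at 0.44, 0.43 and 0.52 for leukocytes, and at 0.07, 0.24 and 0.15 for the thick ascending limb. Carry-over of single cell types predicts that their brightest markers rise together; over the 5 raised lists the lowest median of the 3 brightest markers was 0.06, which leaves carry-over as a common cause undecided. In thick ascending limb, intercalated cells, podocytes and leukocytes that median was 0.25 or more, as carry-over and a change in these cells both predict. In the distal convoluted and connecting tubule Slc12a3 was at −0.12 (95% interval −0.33 to 0.09) and Klk1 at 0.06 (−0.12 to 0.24). Calb1 was at 0.44 and Pvalb at 0.46 in the same list. The other kept probe sets of Calb1, all dimmer, were at 0.77, 0.77 and 1.23, and those of Klk1 at 0.06, −0.06 and 0.04. Whether the brightest probe sets understate changes was not tested. The split into separate lists was made with these values known, so it cannot decide on carry-over of these cells. Carry-over and a response of the kidney to the loss of Clcn5 stay open for all 5 lists, as do invading leukocytes for the leukocyte list.

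Early response genes were higher in knockout by a mean log2 change of 0.40. A single deviating knockout array is argued against, since the mean stayed at 0.38 or more after leaving out each knockout array. Longer handling of the tissue before RNA extraction remains a candidate explanation: it predicts that heat shock and immediate early genes rise together. The 4 heat shock genes had a median of 0.25 and the 7 immediate early genes of 0.40. All of them are members of the list whose rise is to be explained, where 19 of 20 tested genes were above 0. Their rise was thus largely given by that of the list and cannot tell handling from a response to the knockout. The median SE of a single gene was 0.07 and 0.08, which is not the SE of these medians. Of the heat shock genes, Hspa1a, Hspa1b and Dnajb1 did not pass limma's threshold (adjusted p = 0.0937, 0.11 and 0.161). A response to the loss of Clcn5 itself is not excluded and was not tested.

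The 6 arrays can be split into 3 and 3 in 10 ways, and 1 of them, the real one with 753 genes, reached that count; the highest count of the others was 0. So few splits cannot give a share under 0.05.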

How the results depend on the processing

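The fit within station 1 alone and fry in its mixed form were chosen after the data were seen. Clcn5 kept its direction and its call in every alternative, with a log2 change of −1.71 to −1.43 when 1 array was left out. The count of 753 changed genes fell to 487 with variances moderated without a trend (236 higher), to 468 with an unadjusted p under 0.05 and 1.5-fold change (212 higher), and to 453 within station 1 (212 higher, 241 lower), where fewer arrays were used. Leaving out 1 array gave 512 to 733 changed genes, 248 to 340 higher and 246 to 396 lower, and 8 to 11 lists. Other alternatives stayed within 1.5 times of the main counts, from 644 changed genes with no filter to 1099 at an adjusted p under 0.10. The share of higher genes was 45.3% to 53.7%. The 9 shifted lists became 22 with each probe set tested on its own, where a gene counts several times, 0 with an estimated correlation and 32 in fry's mixed form, which asks a different question. The lists of the unfolded protein response, the thick ascending limb and the distal convoluted and connecting tubule lost their calls in 2, 3 and 1 of 20 settings tested with the preset correlation, and the other 6 kept theirs in all 20. Apart from the probe set switches and new test questions named here, the cause was not tested.

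The array numbers do not pair the arrays: deviations from the group means correlated at 0.02, 0.03 and −0.03 for equal numbers. A replicate block gave 765 changed genes, 676 of them among the 753, and 9 lists. Of the 140 genes named besides Clcn5, 96 passed. Over 2770 values under alternatives, 2536 kept direction and side of the threshold, 204 lost the call, 25 gained it, 5 moved without a call and 0 reversed. Leaving out 1 array ended the call of 26 of the 96. The other 70 kept theirs, F5 only in the 3 of 6 cases where it passed the filter. Dim signals limit the largest folds: with 50 added to each signal Cyp4a14 was at −3.79 and Slc10a2 at 2.40, and with a floor of 32 Slc10a2 was at 3.27.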

Other observations

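The tests of gene families and of the added target lists were chosen after other results were seen. Solute carriers, the transporter genes whose symbols start with Slc, changed more often than other genes: 36 of 261 tested, 13.8%, of which 18 rose and 18 fell (odds ratio 2.37, 95% interval 1.61 to 3.42, Fisher's exact test, adjusted p = 0.00146 over 86 groups of genes sharing the start of their symbols). No other group passed. The test takes no account of signal strength, and bright genes were called more often: 797 of 8060 under the stricter filter, against 644 of 18193 with no filter. Whether this explains the excess of carriers was not tested. Among the carriers not described above and named after their values were seen, the zinc transporter gene Slc39a8 was 1.80-fold higher (254 ± 28.9 against 141 ± 4.61, SD, n = 3) and Slc6a13, of a GABA and taurine transporter, 1.81-fold higher (509 ± 54.9 against 284 ± 63.2). Slc35a5 was 2.08-fold lower (261 ± 43.0 against 539 ± 54.8), Slc25a20, the carnitine-acylcarnitine carrier of mitochondria, 2.02-fold lower, and the iron exporter gene Slc40a1 1.26-fold lower. The 42 tested genes whose symbols start with Cyp included 7 that fell and none that rose (adjusted p = 0.261).

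Further genes picked after their values were seen moved by 2-fold or more. Ttr, which encodes transthyretin, a filtered plasma protein also made in other organs, was 2.15-fold lower (1520 ± 132 against 3260 ± 79.0), and its 3 other probe sets had log2 changes of −1.35, −1.06 and −1.10. Sdc4, a heparan sulfate proteoglycan, was 2.36-fold higher (2720 ± 232 against 1150 ± 45.4), but its other probe set had a log2 change of 0.08. Mep1b, a brush border metalloprotease, was 2.62-fold higher (396 ± 20.5 against 151 ± 7.97). Psat1, of serine synthesis, and Eif4ebp1, an inhibitor of translation, were 2.22-fold and 2.41-fold lower.

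A hypothesis drawn from Asns, Chac1, Psat1 and Eif4ebp1 is that ATF4, the transcription factor of the amino acid response, was less active in knockout. It was tested on targets whose values had not been looked at. Of 23 tested, 6 fell and 2 rose, and their median log2 change was −0.07, with 19 below 0. The set did not pass fry (p = 0.0789) and had p = 0.00699 by camera with the preset correlation and 0.216 with an estimated one, so the test leaves the hypothesis undecided.

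A second hypothesis is that the fall of PPARα targets goes beyond the genes of the list. Of 26 tested targets whose values had not been looked at, 12 fell and none rose, 23 were below 0, and the median log2 change was −0.24 (fry p = 0.00168, and p = 0.0379 by camera with an estimated correlation, both unadjusted). With an estimated correlation, 7 of the 36 lists tested before also had an unadjusted p under 0.05 by camera, and 0 passed after adjustment. Decr1 and Eci1, of unsaturated fatty acid oxidation, were at −0.44 and −0.52. This is consistent with a lower activity of PPARα in the knockout tubules. A difference in feeding or time of day between the groups could give the same, as could a strain difference, and neither was tested. On the same arrays the medians were −0.14 for S1 and S2 markers, 0.51 for leukocytes and 0.39 for podocytes. How much of the fall comes from a lower share of proximal tubule cells was not tested either.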
